A study of Mus musculus with 12 samples.

How the data were processed

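Gene expression was measured in the hippocampus of male C57BL/6J mice at 3 weeks of age (postnatal day 21) on Illumina mouse bead arrays, with 1 array per sample. Per the labels, 6 samples came from offspring of dams that drank 10% ethanol by choice from 0.5 to 8.5 days after conception, and 6 samples were controls. The titles place the 12 arrays on 2 beadchips, each carrying 3 ethanol and 3 control arrays. The labels do not say whether the arrays of a group came from separate litters, so p-values measure the spread between these samples, part of which may be technical or shared by littermates. Total RNA was isolated with a silica column kit and labelled with Cy3 by the standard Illumina procedure, per the labels' protocols. GenomeStudio 1.9.0 is the tool named in the submitters' processing notes; its settings are not given in the sources used here.

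The deposited table of scanner output gives for each of 45281 probes and 12 arrays a bead intensity on a linear scale. These deposited intensities had not been normalized between arrays: their medians ran from 132.6 to 152.1, and no background had been subtracted. Beside each intensity the deposited table holds a detection p-value, per the file headers. A second deposited table holds the authors' processed intensities, also linear. Every column of it had the same median of 141.6, and each column followed the signal of its own array (Spearman correlation above 0.999) more closely than that of any other array (at most 0.935), so its values were taken as quantile normalized without background subtraction. No other column of values per sample was left unused.

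The scanner intensities were processed with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). Background was removed by the normexp model fitted through the detection p-values, because no negative control beads were used here; an offset of 16 was added, the arrays were quantile normalized and log2 values taken. Probes with a detection p-value under 0.05 on at least 6 of the 12 arrays were kept, which left 21263 probes. The offset by construction draws differences of dim probes towards 0, and quantile normalization removes any shift that all probes share. Probes were named through the platform annotation, with symbols updated through the Entrez number against the GRCm38.p6 gene table: 18064 tested probes had 1 gene, 9 had several and were not named, and 3190 had none in the annotation used here. The named probes covered 11401 genes. No genome build is named for the array, and no coordinates are given. Where a gene had several tested probes, the one with the highest mean signal over the 12 arrays represented it in gene lists.

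Ethanol was compared with control by lmFit and eBayes over all 12 arrays, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Differences are ethanol minus control on the log2 scale, and intervals are 95% intervals of the limma fit unless another fit is named. A set of 29 gene lists with 979 genes, of which 735 had a tested probe, was written before the data were examined. It covers synapses, neuronal subfields, glia, vessels and blood, neighbouring regions a dissection could include, and pathways linked with alcohol exposure. Each list was tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and the mean log2 signal of each list per array was compared by limma and by an exact two-sided permutation test over 924 splits, both added after the data were seen. Counts of list members are given over all probes tested and adjusted over the list alone. The beadchips were compared with group as a term.

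Genes were named by a rule fixed before the data were examined. In each direction up to 12 genes past the threshold were to be named, with up to 6 more by unadjusted p, given as not past the threshold; each gene list described could have up to 4 members named, those past the threshold first and then by p. Slc17a6, the male-expressed genes Ddx3y, Eif2s3y, Kdm5d and Uty, and Xist were always to be named. For lists without a call, the number of members named was limited to 2 after the list values had been seen. Any other gene named was chosen after its values were seen, and this is stated with it.

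The fits were tested on simulated data built from the array values. With 200 probes changed among 21263, 100 at each of 2 sizes, 55.8% of the probes changed by 0.5 on the log2 scale and 93.6% of those changed by 1 were recovered, and 5.76% of the calls were false. A simulated shift of -0.2 in the immediate early genes was called in 5 of 5 simulations, with 0 calls of other lists, whereas other splits of the real arrays called a median of 5 lists. The simulated genes varied independently, while the real immediate early genes correlated at 0.29 over the arrays. The simulation therefore does not show how often lists of correlated genes are called. Before any averaging, arrays were compared with each other: correlations of normalized values ran from 0.9807 to 0.9927, and 0 pairs held identical signals.

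Alternatives planned before the data were examined were no background correction, scaling to a common median, the authors' processed values, no filter on detection, detection on all 12 arrays, beadchip as a block, each beadchip alone, the replicate number as a block, array weights, an intensity trend with a robust prior, averaged probes of a gene, and leaving out each array in turn. A further pair of settings, the mean of the choroid plexus genes as a covariate and the fit without 4 arrays low in Ttr, was chosen after seeing the data. The depth of a bead array is its signal over background: between 20804 and 21672 probes (45.9% to 47.9%) were detected per array, and the number of arrays limits the precision.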

Results

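Messenger RNA was measured in the hippocampus, the forebrain structure of learning and spatial memory, of male C57BL/6J mice at 3 weeks of age. The series holds 6 arrays from mice whose dams drank 10% ethanol by choice from 0.5 to 8.5 days after conception, a window that covers implantation and gastrulation, and 6 control arrays. Ethanol drinking ended before the hippocampus forms, so the comparison asks which transcripts still differed in the juvenile brain after an exposure confined to the earliest days of gestation. The samples were spread over 2 beadchips with 3 ethanol and 3 control arrays on each. Between 20804 and 21672 of the 45281 probes were detected per array, and median signals ran from 132.6 to 152.1. Eif2s3y, a gene of the Y chromosome, was detected on all 12 arrays, as was Kdm5d on 1 of its 2 probes, and Uty was detected on 11 arrays on 1 of its 4 probes. Xist, the transcript of the inactive X chromosome, was detected on 0 of 12 arrays with each of its 4 probes, and no probe was named for Ddx3y. These readings match the male sex given in the labels.

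The widest difference found between the arrays did not follow the groups. Ttr, which encodes the thyroid hormone carrier that choroid plexus epithelium secretes into cerebrospinal fluid, had log2 signals of 8.33 to 11.00 on 4 arrays and of 15.56 to 15.81 on the other 8 arrays. The 4 arrays low in Ttr were ethanol replicates 1 and 3 and control replicates 1 and 4, 2 in each group. The choroid plexus genes Folr1, a folate receptor, Kl, which encodes klotho, Otx2, a homeobox transcription factor, and the water channel Aqp1 split the same 4 arrays from the rest, with Aqp1 at 5.21 to 5.77 against 10.31 to 10.93. In total 16 of 19 tested genes of the choroid plexus and ependyma list separated these 4 arrays from the other 8. The 16 include Ttr, which defined the 4 arrays. All were lower there, where chance gives 0.202% of genes in 1 direction. The 3 that did not separate the arrays were Foxj1, Enkur and Rarres2, of which Foxj1 is a regulator of motile cilia. These arrays also stood apart on the first principal component, which held 28.4% of the variance, and 3 of them lay on beadchip 1. The list mean was 8.66 ± 1.54 in ethanol and 8.64 ± 1.59 in control (SD, n = 6), a difference within the spread between arrays (exact two-sided permutation p = 0.933). The genes of this paragraph other than Foxj1 and Enkur were chosen after their values were seen.

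**Figure D1:**
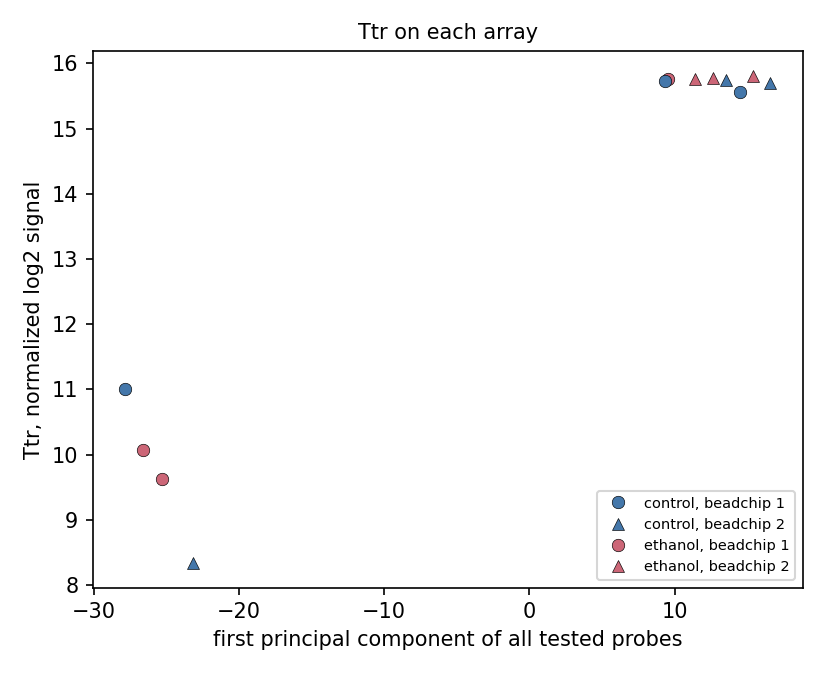
Normalized log2 signal of Ttr on each of the 12 arrays (vertical axis) against the position of the array on the first principal component of all tested probes (horizontal axis, log2 units), with colour for the group and shape for the beadchip. The 4 arrays with Ttr between 8.33 and 11.00 lie at the left, 2 from each group, and the other 8 arrays lie between 15.56 and 15.81.

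Comparing ethanol with control mice asks whether early gestational exposure left a difference in hippocampal gene expression at 3 weeks. No single transcript passed the test. The 6 genes with the smallest p in each direction were higher by 0.40 to 0.54 or lower by 0.36 to 0.49 on the log2 scale, shifts smaller than 1.5-fold. Fam167a was lower in ethanol mice, with a mean log2 signal of 6.38 ± 0.14 against 6.87 ± 0.13 in controls (SD, n = 6), a difference of -0.49 (95% interval -0.67 to -0.30) at an adjusted p of 0.731 by limma. All 6 ethanol arrays were below every control array for Fam167a, and likewise for Amer2, a membrane protein that binds APC in the Wnt pathway, for Tapbp, the tapasin that loads peptide onto class I molecules, for Nab1, a corepressor of the Egr transcription factors, and for Zcchc8 and Wfdc10. On the higher side, all 6 ethanol arrays lay above every control array for Rsbn1l, Tmem241 and 4833438C02Rik, as did 5 of 6 for Pik3r4, the regulatory subunit of the class III lipid kinase of autophagy, and for Macrod2, and 3 of 6 for the histone methyltransferase gene Kmt5b.

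Over all probes, the groups did not overlap for 43, where chance gives about 46. By limma, 0 of 21263 probes passed an adjusted p of 0.05, and the lowest adjusted p was 0.731. At an unadjusted p under 0.05 there were 1022 probes, 522 higher and 500 lower in ethanol, where chance alone gives about 1063. The 95% interval of the difference lay within a 2-fold change for 99.5% of the probes and within a 1.5-fold change for 92.3%, and 0 probes had an absolute log2 difference above 1. Several of the genes above were carried by 1 probe among several: other probes of Kmt5b reached -0.02, of Macrod2 -0.21, of Tmem241 0.06, of Amer2 -0.09, of Tapbp 0.10, of Zcchc8 0.04 and of Nab1 0.09. Tmem241 was detected on 6 of 6 ethanol and 1 of 6 control arrays, 4833438C02Rik on 6 of 6 and 3 of 6, and Wfdc10 on 2 of 6 and 6 of 6, so these sit near the detection limit. Slc17a6, the vesicular glutamate transporter VGLUT2 that a published report on this exposure model studied in adult hippocampus, had log2 signals of 11.77 ± 0.25 in ethanol and 11.70 ± 0.10 in control (SD, n = 6). Its difference of 0.07 (95% interval -0.16 to 0.30) had an adjusted p of 1.00 by limma, and its other probe gave -0.02. Leaving out single arrays moved it from 0.0209 (without ethanol replicate 3) to 0.136 (without ethanol replicate 6). Scaling to a common median in place of quantiles raised the median difference of all probes to 0.05 and turned the split at an unadjusted p under 0.05 to 942 higher and 256 lower, with 0 probes past the threshold.

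**Figure D2:**
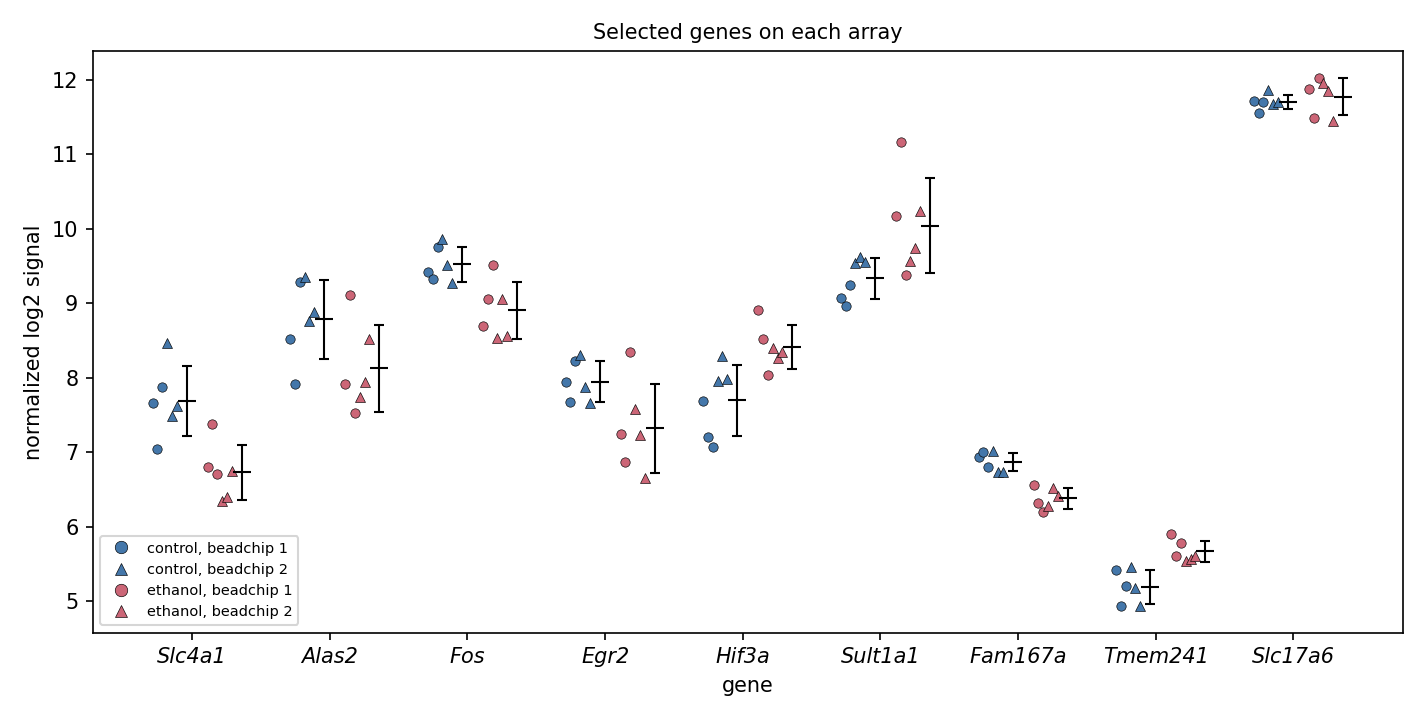
Normalized log2 signal (vertical axis) of 9 genes on each array, with blue for control, red for ethanol, circles for beadchip 1 and triangles for beadchip 2; bars show the mean and SD of 6 arrays. Fam167a and Tmem241 do not overlap between groups, while Slc17a6 lies at 11.77 in ethanol and 11.70 in control.

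Genes of red blood cells had the lowest difference of the 29 lists. All 7 tested members of the erythroid list were lower in ethanol mice, and the list mean was 10.23 ± 0.32 against 10.73 ± 0.26 (SD, n = 6), a difference of -0.50 (95% interval -0.84 to -0.16) with 5 of 6 ethanol arrays below the control mean. Slc4a1, the band 3 anion exchanger of the red cell membrane, differed by -0.96 (95% interval -1.42 to -0.50, fold 0.515). Alas2, the first enzyme of haem synthesis in erythroid cells, differed by -0.66, the ubiquitin-conjugating enzyme gene Ube2l6 by -0.51, and Hbb-bt, an adult beta globin whose near-identical copy Hbb-bs can share its signal, by -0.48 on its brightest probe. Slc4a1 and Ube2l6 passed the threshold adjusted over the list alone (adjusted p = 0.0037 and 0.0131 by limma), and 0 members passed it over all probes. For each of the pair, 5 of 6 ethanol arrays lay below every control array. Bpgm, the enzyme of 2,3-bisphosphoglycerate synthesis, did not share the shift, at -0.01; it was chosen after its value was seen. The list passed camera at its preset correlation (adjusted p = 6.68e-07) but not with the correlation estimated from the arrays (adjusted p = 0.352 with an estimated correlation), and the exact permutation of list means gave p = 0.0195 before and 0.565 after adjustment over 29 lists. Within the beadchips the difference was -0.34 on beadchip 1 and -0.66 on beadchip 2. With beadchip as a block it was -0.50, but each beadchip carries 3 arrays of each group, so the block cannot move a difference. Without the 4 arrays low in Ttr, a fit chosen after seeing the data, the erythroid difference was -0.358 (adjusted p = 0.00321 by camera at the preset correlation).

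Immediate early genes, which neurons switch on within minutes of activity, were lower on balance. Of 21 tested members 17 were lower in ethanol mice, and the list mean differed by -0.17 (95% interval -0.36 to 0.02), with 5 of 6 ethanol arrays below the control mean. Fos had a log2 signal of 8.90 ± 0.38 in ethanol against 9.52 ± 0.24 in control (SD, n = 6), a difference of -0.62 (95% interval -0.97 to -0.27), with 5 of 6 ethanol arrays below every control array. It was the single member past the threshold adjusted over the list alone (adjusted p = 0.0421 by limma), with 0 over all probes. Egr2, a zinc finger factor of synaptic plasticity, differed by -0.62, Fosb by -0.48 and the orphan nuclear receptor gene Nr4a2 by -0.31, and these 3 did not pass either adjustment. Camera called the list at the preset correlation (adjusted p = 0.000197) and not otherwise (adjusted p = 0.772 with an estimated correlation; exact permutation p = 0.0909, n = 6 per group). Within beadchip 1 the difference was -0.105 (adjusted p = 0.156 by camera) and within beadchip 2 -0.24 (adjusted p = 1.64e-05). With the block it was -0.17, as the balance of the beadchips fixes.

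Genes that respond to glucocorticoids, the adrenal stress hormones, formed the 1 list called higher in ethanol mice. Of 29 tested members 19 were higher, and the list mean differed by 0.118 (95% interval -0.00275 to 0.238), with 6 of 6 ethanol arrays above the control mean. Hif3a, a hypoxia-inducible factor subunit, differed by 0.71 (95% interval 0.28 to 1.14), the sulfotransferase gene Sult1a1 by 0.71 (0.17 to 1.24), the kinase gene Map3k6 by 0.46 and the astrocyte connexin gene Gjb6 by 0.17, none of them past the threshold over all probes or adjusted over the list alone. These are values of the brightest probe, and the other probe gave 0.249 for Hif3a and 0.241 for Map3k6. The list passed camera at the preset correlation (adjusted p = 0.0133) but not otherwise (adjusted p = 0.814 with an estimated correlation). The difference was 0.26 on beadchip 1 and -0.025 on beadchip 2, where the direction turned. With the block it was 0.118, as the balance of the beadchips fixes. The difference between the beadchips was not tested. The call ended without control replicate 3 (adjusted p = 0.248), control replicate 2 (0.174) or ethanol replicate 2 (0.0529).

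The other 4 lists that camera called at the preset correlation were all lower in ethanol mice and smaller in size. None was called otherwise (adjusted p = 0.772 for ribosomal proteins and heat shock, 0.814 for interferon and 0.840 for microglia with an estimated correlation). Ribosomal protein genes of the cytosol differed by -0.0554 (95% interval -0.115 to 0.00402), with 40 of 51 members and 6 of 6 ethanol array means lower; Rpl13a differed by -0.34, Rps12 by -0.16, Rps6 by -0.15 and Rps26 by -0.14. Heat shock and unfolded protein response genes differed by -0.11 (-0.24 to 0.02), with 21 of 31 lower. Among them were Chordc1 at -0.32, the chaperone gene Hsph1 at -0.28 and Xbp1, the transcription factor of endoplasmic reticulum stress, at -0.27, while Hspa1b was higher at 0.28. Interferon and inflammation genes differed by -0.10 (-0.31 to 0.11), with 17 of 27 lower. These included Isg15 at -0.47 (-0.292 without control replicate 4), the endotoxin receptor gene Tlr4 at -0.33 (detected on 2 of 6 ethanol and 4 of 6 control arrays), the chemokine gene Ccl4 at -0.29 (3 of 6 and 4 of 6) and B2m, the class I light chain, at -0.18. Microglia genes differed by -0.06 (-0.18 to 0.05), with 19 of 24 lower, such as Olfml3 at -0.31, Gpr34 at -0.27 and the complement gene C1qb at -0.10, while Ctss, the lysosomal cathepsin S, was higher at 0.25. Without ethanol replicate 1 alone, Rpl13a was at -0.224, Chordc1 at -0.195, Hsph1 at -0.181, Olfml3 at -0.155 and Gpr34 at -0.165. That array stood apart on the second principal component, at -32.08 where the others ran from -7.21 to 18.85. On their other probes Rps12 was at -0.0191, Gpr34 at -0.0809 and B2m at -0.161. None of these members passed the threshold over all probes or adjusted over the list alone.

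The adjusted p of these 4 lists by camera was 0.000327 for ribosomal proteins, 0.00176 for heat shock, 0.0133 for interferon and 0.0301 for microglia. With an estimated correlation 0 of 29 lists passed, and 0 passed by fry, by limma on the list means or by permutation. At an unadjusted p under 0.05 these gave 1, 2, 1 and 2 lists. The permutation, with a smallest possible p of 0.00216, could not pass a single list after adjustment over 29. Within beadchip 1 and beadchip 2 the differences were -0.06 and -0.05 for ribosomal proteins, -0.07 and -0.15 for heat shock, -0.06 and -0.14 for interferon and -0.14 and 0.01 for microglia. The beadchip block left each as it was, which the balance of the groups over the beadchips fixes in advance. Heat shock was not called on beadchip 1 (adjusted p = 0.414 by camera), interferon on neither beadchip (0.167 and 0.108) and microglia not on beadchip 2 (0.855). Without the 4 arrays low in Ttr, a fit chosen after seeing the data, the heat shock difference was -0.03 (adjusted p = 0.566 by camera), and the interferon and microglia calls ended (adjusted p = 0.201 and 0.195). Without ethanol replicate 1 alone the heat shock difference was -0.0727 (adjusted p = 0.023). The interferon difference was -0.02 without control replicate 4 (adjusted p = 0.501), and its call also ended without control replicate 2 (0.105) or ethanol replicates 2 (0.0529), 3 (0.0728) or 6 (0.0602). It ended as well with no filter on detection (-0.0608, 0.178) and with detection on all 12 arrays (-0.0673, 0.161). The microglia call ended without ethanol replicates 1 (-0.0346, adjusted p = 0.215), 2 (0.183) or 5 (0.143) or control replicates 2 (0.175), 3 (0.118) or 4 (0.138). It also ended with no filter on detection (-0.0565, 0.0865), with array weights (-0.0529, 0.069) and with scaling to a common median (-0.01, 0.0511), which raised the median of all probes to 0.05.

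**Figure D3:**
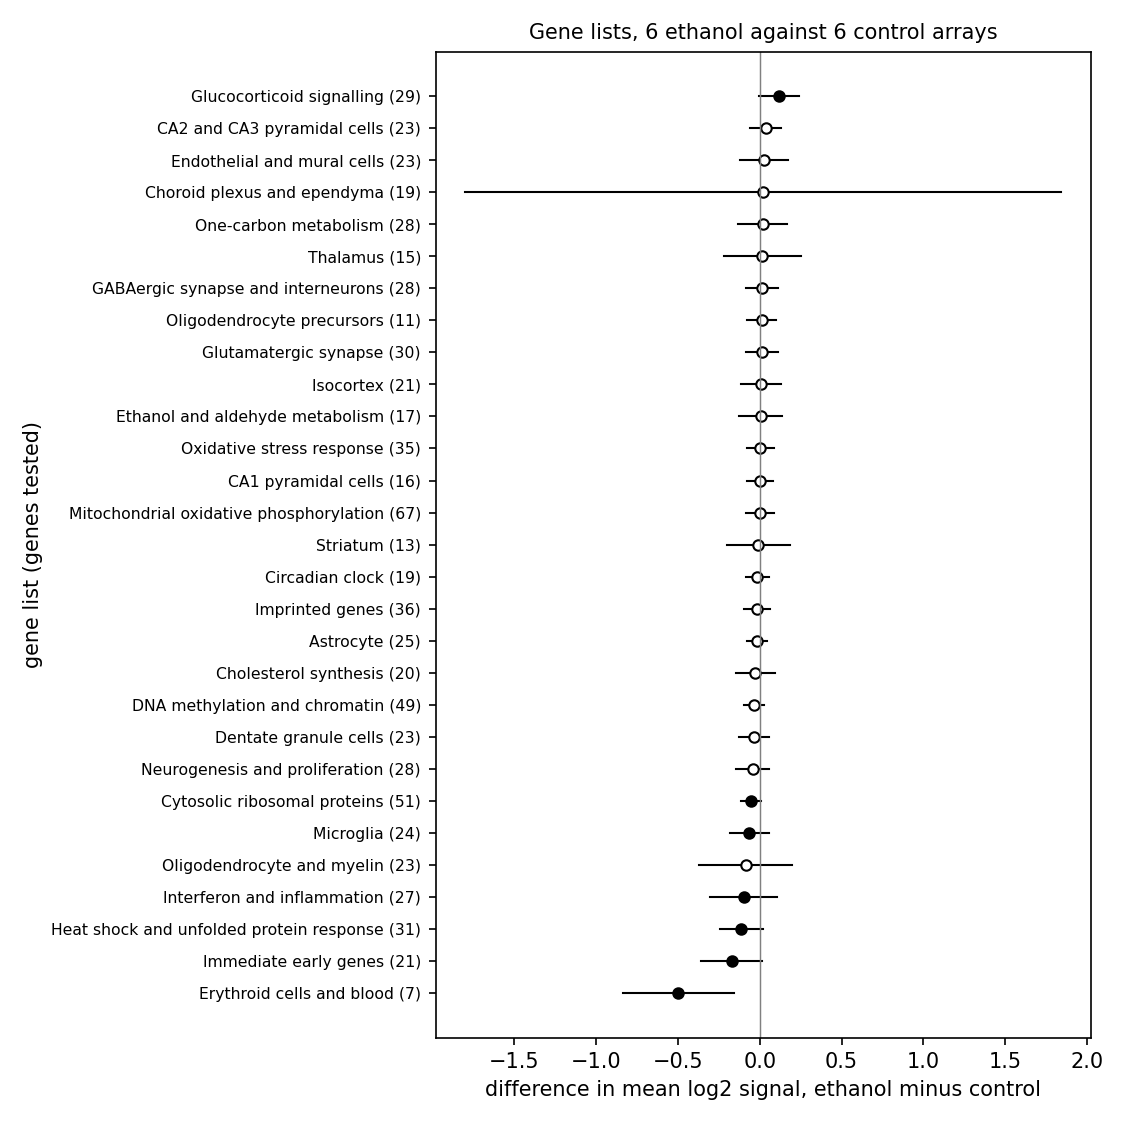
Difference in mean log2 signal between 6 ethanol and 6 control arrays (horizontal axis) for each of 29 gene lists (vertical axis, with the number of genes tested); lines are 95% intervals from limma on the list means, and filled points mark lists past an adjusted p of 0.05 by camera at the preset correlation. The erythroid list lies lowest at -0.50, the glucocorticoid list highest at 0.12, and the interval of the choroid plexus list runs from -1.80 to 1.84.

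**Figure D4:**
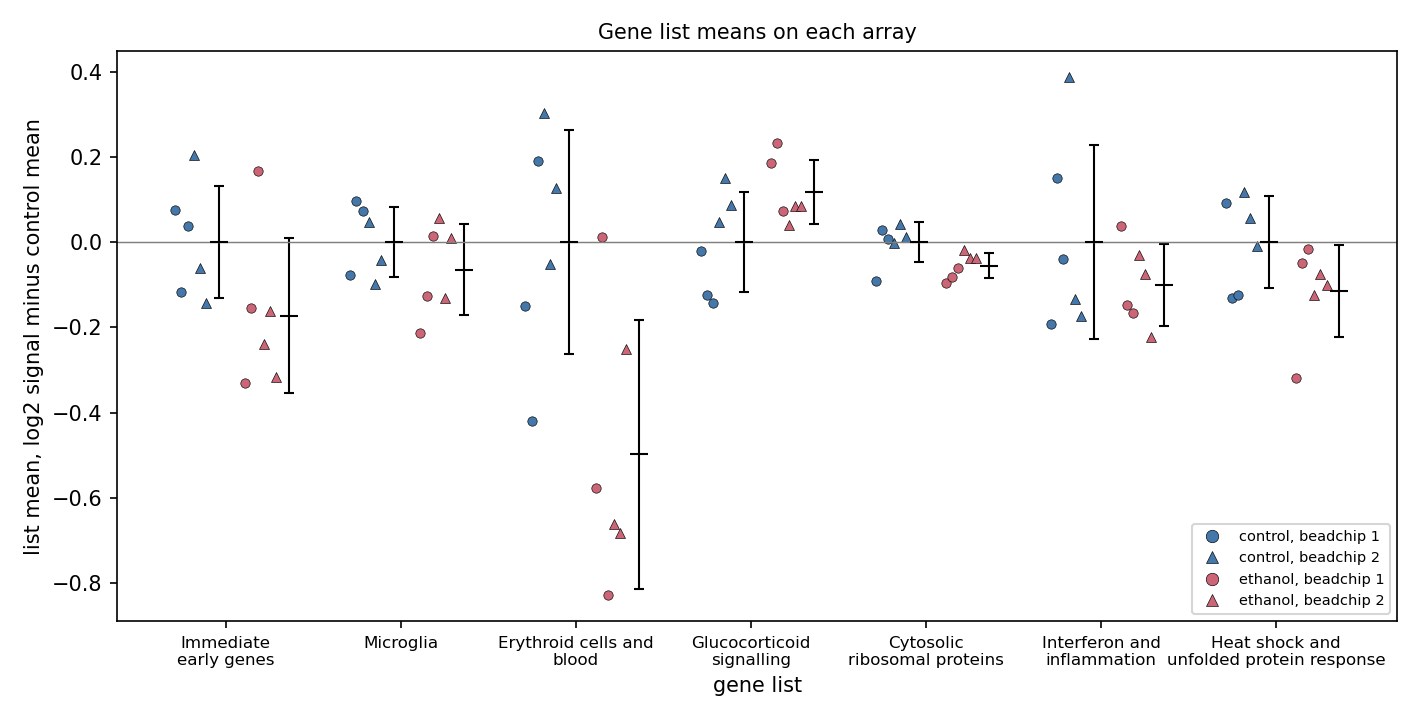
Mean log2 signal of each of the 7 called lists on each array, minus the mean of the 6 control arrays (vertical axis); circles are beadchip 1, triangles beadchip 2, and bars give the mean and SD of 6 arrays. In the erythroid list 5 of 6 ethanol arrays lie below the control mean, and in the glucocorticoid list all 6 lie above it.

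No neuronal gene list was called between ethanol and control mice. The list means of the glutamatergic synapse (difference 0.01, 95% interval -0.09 to 0.11), of GABAergic synapses and interneurons (0.01, -0.08 to 0.11), and of dentate granule cells (-0.04, -0.13 to 0.05), CA1 pyramidal cells (0.00, -0.08 to 0.08) and CA2 and CA3 pyramidal cells (0.04, -0.06 to 0.13) had intervals that held 0 and excluded differences beyond 0.131 in either direction. Examples were the kainate receptor gene Grik4 at 0.25 and the AMPA receptor gene Gria4 at 0.28, the neuronal nitric oxide synthase gene Nos1 at -0.19 and the neuropeptide gene Cck at -0.14, Rasl10a at -0.29 and Fam163b at 0.37 among dentate genes, Ccn3 at 0.25 (0.106 without control replicate 6) and Pou3f1 at 0.11 (0.0424) for CA1, and Spock1 at 0.12 for CA3. Markers of neighbouring regions were not called, at 0.01 (-0.22 to 0.25) for thalamus, with Tcf7l2 at -0.27 and Tnnt1 at 0.26 (0.142 without ethanol replicate 3), -0.01 (-0.20 to 0.18) for striatum, with Scn4b at 0.13 and Rarb at -0.11, and 0.01 (-0.12 to 0.13) for isocortex, with Rprm at 0.26. Without ethanol replicate 5, Scn4b was at 0.0786 and Rarb at -0.0487, and without control replicate 3 Spock1 was at 0.0722. On their other probes Nos1 was at 0.0147, Ccn3 at -0.128, Tcf7l2 at -0.0812, Fam163b at 0.185 and Gria4 at 0.203. Those of Scn4b (0.246) and Rarb (-0.191) were farther from 0.

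Apart from microglia, the glial and vascular lists were not called. Astrocyte genes differed by -0.02 (95% interval -0.08 to 0.04), although Aqp4, the water channel of astrocyte endfeet, was at -0.41 (-0.69 to -0.13), and its adjusted p over the list alone was 0.184 by limma. Oligodendrocyte and myelin genes differed by -0.09 (-0.37 to 0.20), with Pllp at 0.21 and Nkx6-2 at -0.26 (0.125 and -0.126 without ethanol replicate 1). That list was not called (adjusted p by camera 0.0785, and 0.989 with an estimated correlation). At the preset correlation its difference was -0.309 on beadchip 1 (adjusted p = 2.68e-09) and 0.135 on beadchip 2 (0.0211), and it was called without ethanol replicates 2 (0.0388), 4 (0.000191) or 5 (0.00997) or control replicates 2 (0.0241) or 4 (0.000769). It was also called with no background correction (0.0499), the authors' values (0.0498), scaling to a common median (0.013), the mean of the probes of a gene (0.0386) and the choroid plexus covariate (0.0394). Without ethanol replicate 1 its difference was -0.0135. Oligodendrocyte precursor genes differed by 0.01 (-0.08 to 0.10), with the growth factor receptor gene Pdgfra at 0.19 and Matn4 at 0.19. Endothelial and mural cell genes differed by 0.03 (-0.12 to 0.17), with Pecam1 at 0.21 and Kcnj8 at 0.31; on beadchip 1 the difference was -0.134 (adjusted p = 0.00377) and on beadchip 2 0.185 (4.74e-05), both at the preset correlation (0.989 over all 12 arrays with an estimated correlation). The choroid plexus list differed by 0.02 (-1.80 to 1.84), with Foxj1 at -0.34 (detected on 2 of 6 ethanol and 4 of 6 control arrays) and Enkur at 0.14 (0.0616 without ethanol replicate 2, 0.235 without control replicate 3). It was at -1.01 on beadchip 1 and 1.05 on beadchip 2, at -0.436 without control replicate 4 (adjusted p = 0.0355) and at 0.456 without ethanol replicate 3 (0.232). With an estimated correlation its adjusted p over all 12 arrays was 0.989.

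The lists of alcohol metabolism, one-carbon metabolism, chromatin, imprinting and neurogenesis were not called. The list means were 0.00 (95% interval -0.13 to 0.14) for ethanol and aldehyde metabolism, with Aldh18a1 at -0.18 (-0.11 without ethanol replicate 2) and Aldh1b1 at 0.24 (0.129 without control replicate 4); 0.02 (-0.13 to 0.17) for one-carbon metabolism, with Fpgs at 0.19 and Gldc at -0.14 (-0.0915 without ethanol replicate 1); and -0.04 (-0.10 to 0.03) for DNA methylation and chromatin, with the acetyltransferase gene Kat2b at 0.40 and the remodeller gene Atrx at 0.25. Other probes gave 0.0521 for Kat2b, as low as 0.0483 for Fpgs and -0.0343 for Gldc. Imprinted genes differed by -0.02 (-0.09 to 0.06). Among them Kcnk9, a potassium channel gene expressed from the maternal allele, was at -0.45 with all 6 ethanol arrays below every control array (adjusted p over the list alone 0.0992, limma) but was detected on 3 of 6 ethanol arrays, and Mkrn3 was at 0.41 (0.18 without ethanol replicate 1). Neurogenesis and proliferation genes differed by -0.04 (-0.14 to 0.05), with Nes, the intermediate filament of neural stem cells, at -0.50 (-0.80 to -0.19) and an adjusted p over the list alone of 0.101 by limma, and Prc1, a protein of cell division, at -0.31. That list was called without the 4 arrays low in Ttr, at -0.0976 (adjusted p = 0.0264), and without ethanol replicate 1 (0.0484), but was at -0.0136 without ethanol replicate 5 (0.87) and -0.0254 without ethanol replicate 2 (0.741). The chromatin list was called without ethanol replicate 1 (0.0484) or control replicates 5 (0.011) or 6 (0.0347), but was at -0.016 without control replicate 1 (0.618). With an estimated correlation their adjusted p over all 12 arrays was 0.989 and 0.814.

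Lists of general metabolism and of the clock completed the set. Oxidative stress response genes differed by 0.00 (95% interval -0.08 to 0.08), with Me1 at 0.20 and Mt3 at -0.13, and mitochondrial oxidative phosphorylation genes by 0.00 (-0.09 to 0.09), with Cox7b at 0.27 and Ndufv1 at 0.11. Cholesterol synthesis genes differed by -0.03 (-0.15 to 0.09), with Msmo1 at -0.14 and Abcg1 at 0.11, and circadian clock genes by -0.02 (-0.09 to 0.06), with Nr1d1 at 0.22 and Per2 at -0.15. Without ethanol replicate 1, Msmo1 was at -0.0678, Per2 at -0.0939 and Ndufv1 at 0.0706, and without control replicate 6 Abcg1 was at 0.0398. Cholesterol synthesis was called on beadchip 1, at -0.128 (adjusted p = 0.00437), and oxidative phosphorylation without control replicate 1, at -0.0331 (0.012). With an estimated correlation the adjusted p of both over all 12 arrays was 0.989, and leaving out single arrays moved cholesterol synthesis from -0.0511 (without ethanol replicate 4) to 0.002 (without ethanol replicate 2). Scaling to a common median raised the median of all probes to 0.05, more than the size of the means that follow. With that shift the means of the astrocyte, striatum, dentate, chromatin, imprinted, clock and cholesterol lists took the other sign. None of the 22 lists without a call held a member past the threshold, over all probes or adjusted over the list alone. In 6 of the 29 lists (oligodendrocyte precursors, choroid plexus, striatum, CA1, oxidative stress and oxidative phosphorylation) the mean, the median and the direction of camera differed in sign.

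The 2 beadchips differed in few transcripts. With group as a term, 6 of 21263 probes passed an adjusted p of 0.05 by limma, 5 higher and 1 lower on beadchip 2. Kat7, a histone acetyltransferase gene, differed by -0.70 between beadchip 2 and beadchip 1 (mean log2 signal 5.26 against 5.96, adjusted p = 0.0199), while Ndufb10, a subunit of complex I, was higher by 0.55 (adjusted p = 0.0443) and the kinase gene Araf by 0.44 (adjusted p = 0.0479). The 3 other probes had no gene in the annotation used here. These genes were chosen after their values were seen. Without background correction and with the authors' values the count was 26.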

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

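Each value here lay farther from the other 5 arrays of its group than Dixon's test allows at the 95% level, which compares the gap to the nearest value with the range of the group. Of 228 groups of 6 values tested, 18 did so, and chance gives about 1 in 20. Of the 18, 10 were on the 4 arrays low in Ttr.

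Among the called gene lists, the mean of the immediate early genes was 9.49 on ethanol replicate 3 against 9.17 or less on the other ethanol arrays, which places this array above the other ethanol mice and against the direction of the list. The heat shock and unfolded protein response mean was 9.78 on ethanol replicate 1, with the other ethanol arrays at 9.97 or more, and the heat shock gene Chordc1 was 10.67 there against at least 11.30. The ribosomal protein mean was 12.82 on control replicate 1, against at least 12.91, and the oxidative phosphorylation mean on the same array was 12.09 against at least 12.26. The oligodendrocyte precursor mean was 8.83 on ethanol replicate 4, above the 8.69 or less of the others. Fosb was 6.50 on control replicate 2, where the other controls had at least 7.06, and Hspa1b was 6.63 on ethanol replicate 3 against at least 7.09. The microglial gene Ctss was 7.66 on control replicate 3, above at most 7.32.

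Of the genes with the smallest p in each direction, Rsbn1l was 6.36 on ethanol replicate 4 (others at most 6.07), Kmt5b 6.52 on control replicate 1 (at most 6.10) and Nab1 6.83 on ethanol replicate 6 (at least 6.92). In the remaining lists, Nos1 was 7.87 on control replicate 3 (others at least 8.37), Tnnt1 7.12 on control replicate 5 (at most 6.85), Pou3f1 10.28 on control replicate 6 (at least 10.64) and Kat2b 6.10 on ethanol replicate 3 (at least 6.62). Per2 was 10.42 on ethanol replicate 1 (others at least 10.68), and Msmo1 was 11.63 on control replicate 4 (at least 11.89).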

How the results depend on the processing

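The choroid plexus covariate, the fit without 4 arrays low in Ttr, the permutation of list means and limma on list means were chosen after seeing the data. Under every alternative run, 0 probes and 0 list members passed the threshold over all probes, including when each array was left out in turn (0 to 0); at an unadjusted p under 0.05 the count ran from 789 on beadchip 1 alone to 1437 on beadchip 2 alone, and was 2087 of 45281 with no filter on detection. Of the 7 gene lists that camera called at the preset correlation, 0 were called with an estimated correlation, by fry, by permutation of list means or by limma on list means. For the permutation, whose smallest possible p is 0.00216, a single list could not pass after adjustment over 29 lists. The genes of the called lists correlated at 0.11 to 0.43 over the arrays, above the preset 0.01, and each of these tests allows for such correlation. Other settings gave 5 to 8 lists, as did leaving out single arrays (5 to 8). On beadchip 2 alone the microglia difference turned to 0.01 and the glucocorticoid difference to -0.025; the cause was not tested. List members past the threshold adjusted over the list alone numbered 3, but 8 without background correction or with the authors' values, 7 with detection on all 12 arrays, beadchip as a block or the choroid plexus covariate, 9 on beadchip 2 alone, and 2 to 16 leaving out single arrays, with 16 without ethanol replicate 3, 8 without control replicate 2 and 6 without ethanol replicate 2 or 6; the cause was not tested. The differences between the beadchips numbered 26, not 6, without background correction and with the authors' values; the cause was not tested.

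Whether replicate numbers pair the samples could not be told. Same-numbered arrays correlated at 0.33, 0.11, -0.25, -0.20, 0.21 and 0.12 over their deviations from the group means, and number 1 alone correlated best with its own number. The pairs below 0, of numbers 3 and 4, each joined an array low in Ttr with an array that was not. The deviations were not adjusted for that split, so the check cannot decide. With the replicate number as a block, 0 probes passed (1078 at an unadjusted p under 0.05), 7 lists were called by camera and 4 list members passed adjusted over the list alone. Of 2114 values of named genes under alternatives, 12 had the other sign, none of them past the threshold. Signal over background limits what was tested: 24018 of 45281 probes were not detected on enough arrays.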

Other observations

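Chosen after the result was seen were the vessel test, the choroid plexus covariate, the fit without 4 arrays, the split test for probes, the variable genes, and the histone group with every test of it but the haemoglobin covariate. The criterion for the histone classes was also revised after its result was seen. The choroid plexus test was changed from the covariate, near equal between the groups, to the fit without 4 arrays. Its criterion was revised to an interval without 0, which shows a difference on the arrays kept but not its cause. Intervals in this part come from ordinary linear models of means per array, not from limma. Replication-dependent histone genes, which encode histones made during DNA synthesis and lie in clusters of near-identical copies, formed a group that was in none of the 29 lists. The group held genes of the 4 core classes and the linker histone genes H1f2 and H1f5. Of 39 such genes with a tested probe, 37 were below 0 in ethanol minus control, H3c13 by 0.00, and 2 above. H2ac15 differed by -0.42 (SE 0.10), H2ac7 by -0.35 (SE 0.09), H2ac24 by -0.33 (SE 0.09), H3c7 by -0.48 (SE 0.17) and H4c17 by -0.51 (SE 0.18), and 0 passed the threshold over all probes, while 14 were lower at an unadjusted p under 0.05 by limma and 3 passed the threshold over the group alone. The mean over the 39 genes was 9.06 ± 0.24 in ethanol and 9.30 ± 0.12 in control (SD, n = 6), lower in 6 of 6 ethanol arrays than the control mean (exact permutation p = 0.0173). Camera gave an adjusted p of 1.05e-15 at the preset correlation and 0.595 with an estimated correlation. These p-values were computed on genes grouped because they were lower, so they carry no weight as evidence. The difference was -0.29 on beadchip 1 and -0.19 on beadchip 2, and ran from -0.27 to -0.15 leaving out single arrays; it was -0.17 without background correction and -0.19 with scaling to a common median.

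A few genes varied over a wide range within both groups. Isl1, a LIM homeobox transcription factor, had log2 signals of 4.66 to 7.53 over the ethanol arrays and 4.59 to 8.37 over the control arrays. Lbhd2 ranged from 4.72 to 8.52 and from 4.67 to 9.14, and Zic1, a zinc finger transcription factor, from 8.10 to 10.10 and from 7.90 to 10.60. Isl1 and Lbhd2 were each detected on 7 of 12 arrays, so their low ends lie near the detection limit, while Zic1 was detected on all 12. Among the 24018 probes left out by the detection filter, 1 was detected on 5 ethanol and 0 control arrays and 2 (for Safb and Gabpb2) on 5 control and 0 ethanol arrays, fewer than the median of 7 over 100 random splits.

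The lower erythroid list may reflect how much blood the tissue held. The brightest haemoglobin probe of Hbb-bt had a log2 signal of 14.94 in ethanol and 15.42 in control, near the top of the range. All 11 haemoglobin probes differed by -0.512 (95% interval -1.06 to 0.037), and the 2 below a log2 signal of 14 by -0.636 (-1.43 to 0.154). With those 2 as a covariate in a linear model, the other 4 erythroid genes differed by -0.33 (-0.59 to -0.06) where they had differed by -0.53 (-0.86 to -0.20). A covariate of 2 probes may adjust incompletely, so blood may account for part or all of the difference and stays open. Fewer vessels would lower endothelial genes too, but that list differed by 0.0256 (-0.133 to 0.184), an interval that excludes a drop as large as the erythroid one. Fewer red cells or reticulocytes in exposed mice stays open as a hypothesis, since perfusion and bleeding are not in the labels.

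The immediate early genes were lower and the glucocorticoid list higher in ethanol mice, and 1 candidate explanation is a single state at sampling that moved both in opposite directions. Over the 12 arrays the deviations of the 2 lists from their group means correlated at r = -0.12 (permutation p = 0.703) and rho = -0.16 (permutation p = 0.612), with r = -0.18 without the 2 arrays farthest from the median; this was the 1 relation computed, and r was -0.12 and 0.04 within the beadchips, and so few arrays leave the explanation open. On the 8 arrays not low in Ttr, the values argue against unequal choroid plexus RNA as the whole cause of the lower immediate early genes. The criterion for this was set after the result was seen. The choroid plexus list mean was 8.66 in ethanol and 8.64 in control, so as a covariate it could hardly move a difference and is no test. With it the immediate early difference was -0.171 (95% interval -0.345 to 0.00216). Without that covariate it was -0.172 over all 12 arrays (-0.377 to 0.0319), an interval that holds 0, so whether the list differs over all 12 stays open. Without the 4 arrays low in Ttr, which moved the heat shock list from -0.114 to -0.0348, the immediate early difference was -0.148 (-0.283 to -0.0124). Camera called it there at the preset correlation (adjusted p = 0.00413), but not over all 12 arrays with an estimated correlation (0.772). The glucocorticoid difference was 0.118 without those 4 arrays (-0.0905 to 0.327), 0.118 over all 12 (-0.00895 to 0.244) and 0.118 with the covariate (-0.0173 to 0.252). It was the same without those arrays, and the covariate could hardly move it. Each interval holds 0, so whether the list differs at all stays open. Camera called that list without the 4 arrays at the preset correlation (adjusted p = 0.045), and not over all 12 with an estimated correlation (0.814). The exposure itself, and time of day or handling, were not tested.

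The mean of the histone genes differed by -0.24 (95% interval -0.48 to 0.000237), an interval that holds 0. If they differ, fewer dividing cells is a possible explanation. The neurogenesis and proliferation list, at -0.0448 (95% interval -0.145 to 0.0554), neither shares the difference of -0.24 nor excludes a smaller one. Without the 4 arrays low in Ttr that list was at -0.0976 and called by camera at the preset correlation (adjusted p = 0.0264). It was at -0.0136 without ethanol replicate 5 (0.87) and -0.0254 without ethanol replicate 2 (0.741). Over all 12 arrays its adjusted p with an estimated correlation was 0.989. With the haemoglobin covariate the histone difference was -0.15 (-0.41 to 0.11), so the amount of blood stays open as well. Probes that read near-identical copies of 1 histone class could count a single change many times, but of the 4 core classes, 1 had an interval below 0, that of H2A at -0.27 (-0.48 to -0.06), and H2B at -0.19, H3 at -0.20 and H4 at -0.33 had intervals that held 0, so this explanation stays open. The first criterion, a single class with an interval below 0, was met and would have favoured it, but a missed threshold does not show that the other classes did not differ, so the revised one also asked that their means be far smaller. An effect of the exposure was not tested apart from these.

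Random splits of the 12 arrays into 6 and 6 show how far chance reaches. All 100 splits gave at least the 0 probes of the real one, an outcome that a count of 0 fixes and that says nothing about chance. Of the other splits 5 called any probe, 1 of them 24, more than the exposure; such a count can point to a structure among the arrays, but none was tested and the 4 arrays low in Ttr lay 2 on each side. For gene lists called by camera at the preset correlation, 38 of 100 splits gave at least the 7 of the real split, with a median of 5 in the others and up to 11 in 1, so chance cannot be excluded for that count. For list members adjusted over the list alone, 37 of 100 splits gave at least 3, with up to 29 in another, and chance cannot be excluded there either. For the beadchips, 2 of 100 splits that kept the groups balanced gave at least the 6 probes of the real one, which chance rarely reaches, although 1 other split gave 22.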
